A study of Mus musculus with 6 samples.

How the data were processed

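RNA-seq libraries of biliary epithelial cells from 3 Klf5 LKO and 3 control samples, all after 1 week of DDC, were compared. Per the labels' protocols, single-end libraries were made from 4 ng of total RNA with a low-input cDNA kit, using 10 cycles of pre-amplification and 7 of enrichment PCR. Repeated amplification from little RNA adds noise for low genes, and reads without molecular identifiers are not independent molecules. Groups and replicate numbers were taken from the sample titles, and no sample was left out.

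The reads were aligned to mm10 with TopHat and Bowtie2 and handled with DESeq2, per the submitters' processing notes. The counter, the gene annotation and the filters are not given in the sources used here, so reads of overlapping genes, of genes on opposite strands and of near-identical copies may have been assigned to either. The authors deposited a table of signal per gene and library that is a read count divided by 1 size factor per library. The authors' deposited table of the comparison holds the mean signal, log2 fold changes of Klf5 LKO against control with their standard errors, a Wald statistic (the score, per the file headers), and p-values with adjusted p-values. The log2 fold changes in the authors' deposited table are shrunken towards 0, judged from the values. Every value in the deposited signal columns was a whole multiple of the value of 1 read in its library, within a tolerance of 0.001, in 100% of values. Total reads were recovered in this way: 21810798, 24784167 and 17161087 in Klf5 LKO 1 to 3 and 20066745, 11726934 and 17665210 in control 1 to 3. At these depths, 3 reads, the most that a true count behind 0 reads could plausibly be, correspond to a normalised count of 2.46, 2.24 and 3.19 in Klf5 LKO and 2.76, 4.74 and 3.05 in control. This covers counting error only.

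The design foresaw edgeR for raw counts and limma for normalised values. Because the deposited values are normalised, limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3 was used on log2(value + 1), a pseudocount of 1, for the 13490 genes with a mean of at least 10 over the 6 libraries. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and adjusted p-values in the text are from this limma fit unless another tool is named. Fold changes are on the log2(value + 1) scale, and the replicate number was not a term. The pseudocount understates the change of low genes. Where single libraries hold few or no reads, the change can instead exceed that of the count tests, such as -6.38 for Msln against -4.80 with DESeq2. Count tests on the recovered reads, with DESeq2 1.42.0 (335 genes called), the edgeR 4.0.16 quasi-likelihood test (84 genes) and limma-voom (74 genes), were alternatives.

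There were 29 gene lists, of pathways for biliary epithelial injury and of markers of other liver cells, fixed before the data were examined, as were the tests and the rule for naming genes. They are S phase and DNA replication, G2/M and mitosis, cell cycle inhibitors and p53 targets, biliary epithelial markers, cell junctions, basement membrane, integrins and matrix remodelling, inflammatory cytokines and chemokines, growth factors and receptors, Notch, YAP/TAZ and Hippo, Wnt, bile duct transport, primary cilium, the KLF and SP family, NRF2 and heme stress, cholesterol and fatty acid synthesis, glycolysis, mitochondrial respiration, interferon response, immediate early and dissociation response, unfolded protein response, and markers of hepatocytes, Kupffer cells and macrophages, neutrophils, lymphocytes and NK cells, endothelium, stellate cells and fibroblasts, erythrocytes and platelets, and mesothelium. The 27 lists with at least 5 measured members were tested with camera in limma at its preset correlation of 0.01, adjusted over the 27. Camera compares a list with all other genes, and the estimated correlation between list members was above the preset in every tested list but the mesothelial markers (-0.109). Camera with an estimated correlation and fry, which asks whether a list's own genes move 1 way on balance, were run beside it, and 0 of the 9 called lists stayed called with either.

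Named genes are Klf5; the 10 genes with the largest change in each direction among called genes with no overlap between groups and a mean of at least 100 in the higher group, predicted genes left out; up to 4 called members of each list by p, or 2 as values where none passed; the most abundant hepatocyte, Kupffer, endothelial and stellate markers; and a fixed set of ductal, cell cycle and KLF genes. Some genes that this rule takes are not reported here, though they remain in the counts. Gene positions come from GENCODE M21 on GRCm38, the assembly of mm10, which matched 23309 of 24404 symbols by name. Cyr61 is among those unmatched, and its position is not given.

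The alternatives were 2 other scalings (TMM factors and upper quartile), no filter or a mean of at least 50, pseudocounts of 0.5 and 5, the 3 count methods, a threshold of 0.1, the replicate number as a block, and each library left out in turn. Added after seeing the data were a leukocyte term (the mean log2 value of 9 leukocyte genes, of which 6 are in the macrophage list and 3 in the lymphocyte list), thinning of all libraries to 11726934 total reads, which does not equalise the number of distinct molecules, and camera with an estimated correlation within each setting but DESeq2. Library duplicates were looked for with a chi-square test of counts, whose lowest value between libraries of a group was 14.4 per degree of freedom, so no 2 libraries agreed within sampling noise.

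The scripts were tested on simulated counts with the real means and library sizes for this comparison. Among 13300 genes with 200 changed, 50 at each fold, limma recovered 12% of those changed 1.5-fold, 66% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 11 false calls, and DESeq2 recovered 36%, 74%, 98% and 100% with 46 false calls. With no gene changed among 13314, limma called 0, voom 0, edgeR 1 and DESeq2 5. A planted list of 40 genes changed 1.5-fold among 13308 was called by camera with either correlation and by fry, and 0 of 20 unchanged lists were called by any of them. The simulated genes were drawn independently of each other. These list results therefore do not cover lists whose members move together, as in the real data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.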

Results

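RNA from biliary epithelial cells, the cells that line the bile ducts inside the liver, was sequenced from adult mice after 1 week of DDC, a compound (diethoxycarbonyl-dihydrocollidine) that injures bile ducts. There were 3 libraries from Klf5 LKO mice, which carried a floxed Klf5 gene and an Alfp-Cre transgene that deletes it in liver epithelial cells, and 3 from control mice with the floxed gene and no Cre. Total reads assigned to genes were 21810798, 24784167 and 17161087 in Klf5 LKO libraries 1, 2 and 3, and 20066745, 11726934 and 17665210 in control libraries 1, 2 and 3. The values are read counts normalised by 1 size factor per library, and 17545 of the 24404 listed genes had at least 1 read. Clu, which codes for the secreted chaperone clusterin, took the largest share of reads in every library, from 4.80% to 6.10%. Spearman correlations between libraries lay between 0.965 and 0.985. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Cre was present only in the Klf5 LKO group, so an effect of Cre itself cannot be separated from the loss of Klf5.

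The series asks what changes in injured bile duct cells when Klf5, a zinc-finger transcription factor, is deleted. Klf5 itself (chromosome 14, 99298691 to 99315036, plus strand, mm10) was lower in every Klf5 LKO library. Its normalised count was 2130 ± 162 (SD, n = 3) in control and 1117 ± 122 (SD, n = 3) in Klf5 LKO. The single libraries held 2056, 2018 and 2316 in control and 977, 1192 and 1183 in Klf5 LKO. This is a log2 fold change of -0.93 (SE 0.14, 95% confidence interval -1.24 to -0.63, adjusted p = 0.0103), or 1.91-fold. Counts were made over the whole gene, so reads from exons outside the deleted part are included, and the remaining level does not measure intact transcript. The call ended without control 1, 2 or 3, with adjusted p = 0.0625, 0.0681 and 0.0540, while the log2 fold change stayed between -0.98 and -0.84 whichever of the 6 libraries was left out.

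Of 13490 genes tested, 22 were higher and 66 lower in Klf5 LKO, 88 in all. The lower genes included the laminin chains Lamb3 and Lama3, the calcium-binding protein S100a6 and the sodium pump regulator Fxyd6, which fell by 3.06, 3.58, 2.57 and 4.34 on the log2 scale. The higher genes included the protease inhibitor Serpina1c and the interferon-induced Rsad2, which rose by 1.30 and 1.60. The values of the 3 Klf5 LKO and 3 control libraries did not overlap for any of these 88 genes. Over all tested genes, 2104 (15.6%) did not overlap, against 10% by chance for 3 against 3. The number of calls changed with the libraries used. It was 49 without Klf5 LKO 3, 24 without control 1, 14 without control 2 and 53 without control 3, against 105 without Klf5 LKO 1 and 79 without Klf5 LKO 2. The 22 higher genes became 11 without Klf5 LKO 2, 9 without Klf5 LKO 3, 6 without control 1, 1 without control 2 and 11 without control 3. The 66 lower genes became 40, 18, 13 and 42 without Klf5 LKO 3, control 1, control 2 and control 3. DESeq2 on the recovered reads called 335 genes, of which 35.5% were higher, against 25.0% of the 88.

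**Figure D1:**
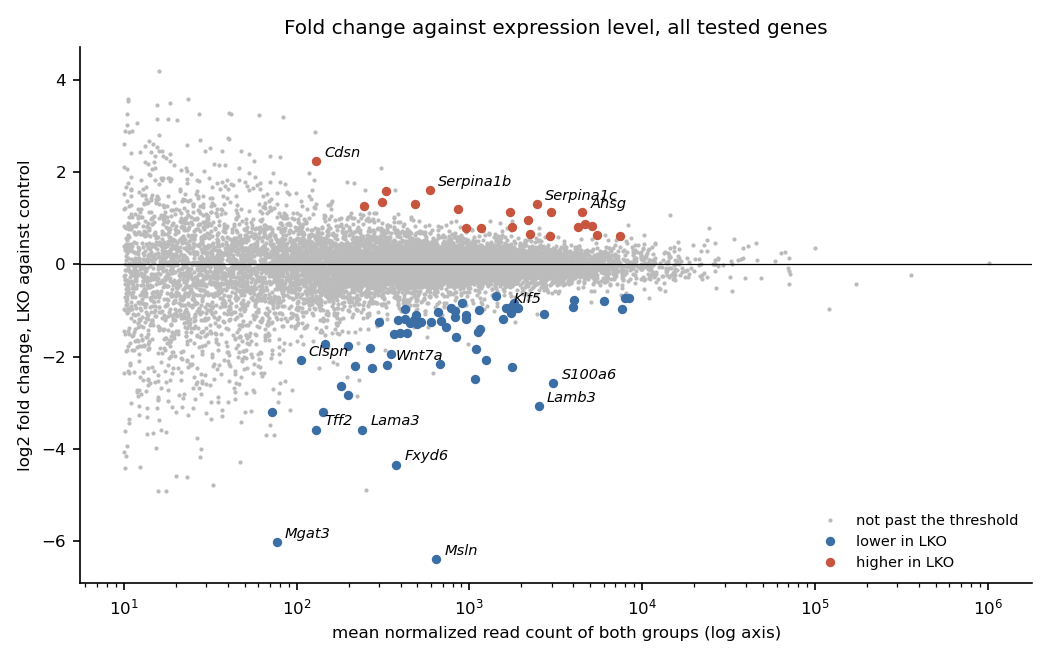
Log2 fold change of Klf5 LKO over control against the mean normalised count (log axis) of each of 13490 tested genes. The 66 genes lower in Klf5 LKO are blue and the 22 higher are red, and the largest changes, such as Lamb3 at -3.06, were downward.

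The laminin genes Lamb3 and Lama3 were among the 10 named genes with the largest decreases. They code for chains of the laminin that anchors epithelial cells to their basement membrane. Lamb3 (chromosome 1, 193207699 to 193343878, plus strand) fell from 4500 ± 410 to 544 ± 112 normalised counts (SD, n = 3 each), a log2 fold change of -3.06 (SE 0.17, adjusted p = 6.46e-06) or 8.36-fold. Lama3 (chromosome 18, 12333819 to 12583013, plus strand) fell from 442 ± 49.5 to 37.1 ± 12.0, or 11.9-fold (adjusted p = 0.000310). In the list of 44 basement membrane, integrin and matrix remodelling genes, all measured, these 2 fell, 0 rose and the other 42 did not pass, and adjusted over the list alone 3 fell and 0 rose. The list as a whole was not called (adjusted p = 0.123; median log2 fold change -0.04). It was called without Klf5 LKO 2 (adjusted p = 0.0118), without control 1 (adjusted p = 0.0298), and with the fold changes of DESeq2 (adjusted p = 0.00313) or edgeR (adjusted p = 0.00599), and with a term for leukocyte transcripts (adjusted p = 0.0147). With an estimated correlation the list was not called over all libraries (adjusted p = 0.770), without Klf5 LKO 2 (0.667), without control 1 (0.683), with edgeR (0.681) or with the leukocyte term (0.558), and for DESeq2 none was estimated.

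S100a6 (chromosome 3, 90612882 to 90624181, plus strand) fell from 5217 ± 824 to 887 ± 204, a log2 fold change of -2.57 (adjusted p = 3.95e-05), and the related calcium-binding gene S100a14 on the same chromosome fell by 2.83 (adjusted p = 0.00446). Fxyd6 (chromosome 9, 45370185 to 45396159, plus strand), a regulator of the sodium pump, fell from 717 ± 209 to 34.4 ± 9.82, or 20.2-fold (adjusted p = 7.66e-05). Tff2, a trefoil peptide secreted with mucus, fell from 240 ± 52.7 to 20.3 ± 8.82, and the lipid-anchored surface protein Ly6d from 314 ± 82.3 to 50.2 ± 14.2. Samd5 fell from 130 ± 44.1 to 14.9 ± 9.50. Mgat3, a sugar transferase of the secretory pathway, had 1, 3 and 1 reads in the Klf5 LKO libraries and 116, 98 and 192 in control (adjusted p = 0.00319). Msln, a surface glycoprotein of mesothelial cells, had normalised counts of 1242 ± 70.0 in control and 44.6 ± 52.8 in Klf5 LKO, where the libraries held 0, 138 and 29 reads. Its log2 fold change of -6.38 depends on the pseudocount and was -4.43 without Klf5 LKO 1 and -7.78 without Klf5 LKO 2, that of Samd5 went from -3.21 to -2.61 without Klf5 LKO 1, and for Msln DESeq2 gave adjusted p = 0.105. Lamb3, Lama3, S100a6 and Fxyd6 kept their calls whichever library was left out. The calls of Mgat3 and S100a14 ended without control 2 (adjusted p = 0.0699 and 0.0552), of Ly6d without control 1 (adjusted p = 0.0625), and of Tff2 without control 1 or 2 (adjusted p = 0.0525 and 0.0588). Those of Samd5 and Msln ended without Klf5 LKO 3 (adjusted p = 0.0803 and 0.0687), control 1 (0.218 and 0.150), control 2 (0.136 and 0.155) and control 3 (0.182 and 0.127). Other settings also ended calls, that of Mgat3 with voom (adjusted p = 0.0640), that of Samd5 with no filter (0.0866), edgeR (0.0617), voom (0.0812) and thinning (0.0663), and that of Msln with no filter (0.0688) and a pseudocount of 0.5 (0.0610).

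**Figure D2:**
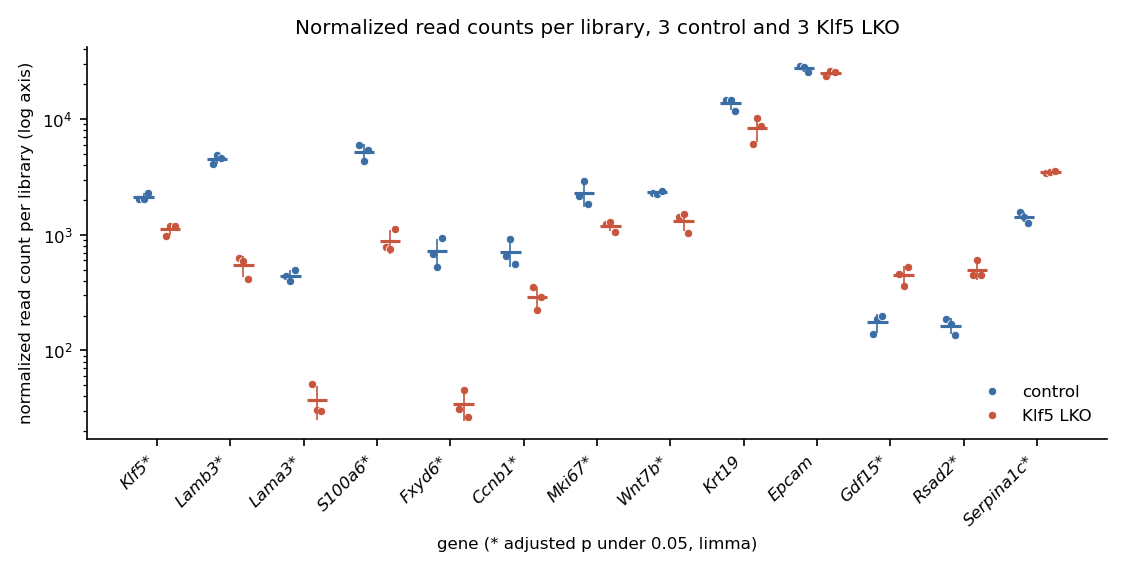
Normalised count (log axis) of 13 named genes in each library, with points for the 3 Klf5 LKO and 3 control libraries, a horizontal bar at the group mean and a vertical line for the SD. A star marks a gene past the threshold: Lamb3 fell from a mean of 4500 to 544 and Serpina1c rose from 1421 to 3498, while Krt19 and Epcam did not pass.

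Among the 10 named genes with the largest increases were Cdsn, Serpina1b, Serpina1c, Rsad2 and Gdf15. Serpina1c (chromosome 12, 103894926 to 103904887, minus strand), a copy of the antitrypsin gene, rose from 1421 ± 143 to 3498 ± 72.9 (SD, n = 3 each), a log2 fold change of 1.30 (SE 0.13, adjusted p = 0.000512) or 2.47-fold. Its neighbour Serpina1b rose from 291 ± 65.6 to 892 ± 189 (adjusted p = 0.00939). The Serpina1 copies are nearly identical, so how the rise divides between them is uncertain. The antiviral gene Rsad2 rose from 164 ± 26.0 to 498 ± 88, and Gdf15, a secreted stress-induced factor, from 175 ± 32.6 to 447 ± 84.2. Cdsn, an adhesion protein of cornified epithelia, had the highest fold change among the named increases, from 46.9 ± 22.2 to 212 ± 40.5. The scaffold Akap12 rose by 1.14 on the log2 scale and the thrombin receptor F2r by 1.20, and the heparan sulphate proteoglycan Gpc3 rose from 145 ± 25.4 to 346 ± 11.2. Serpina1c kept its call whichever library was left out. Without control 2 the calls of Serpina1b, Rsad2 and Akap12 ended, with adjusted p = 0.0588, 0.0588 and 0.0552. That of F2r ended without Klf5 LKO 2 (adjusted p = 0.0551), control 2 (0.0872) and control 3 (0.0524), and that of Cdsn without Klf5 LKO 2 (0.0595), Klf5 LKO 3 (0.129), control 1 (0.130) and control 2 (0.124). The call of Gpc3 ended without each of the 6 libraries in turn, with adjusted p from 0.0590 without control 3 to 0.168 without control 1. Gdf15 kept its call only without Klf5 LKO 2, and its adjusted p without Klf5 LKO 1, Klf5 LKO 3, control 1, control 2 and control 3 was 0.0614, 0.138, 0.151, 0.124 and 0.0619.

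The lists for G2/M and S phase had lower medians in Klf5 LKO and were called with the preset correlation, while 6 of their genes passed singly. All 47 measured genes of the G2/M and mitosis list had lower means, with a median log2 fold change of -0.96, and the list was called (adjusted p = 1.19e-32; adjusted p = 0.501 with an estimated correlation). Over all tested genes 4 fell and 43 did not pass, while adjusted over the list alone 39 fell and 0 rose. In 33 of the 47 the 2 groups did not overlap, where chance gives 10% and all tested genes gave 15.6%, and members that move together (estimated correlation 0.317) are not separate evidence. The mitotic cyclin Ccnb1 fell from 708 ± 183 to 289 ± 64.9, the proliferation marker Mki67 from 2300 ± 551 to 1194 ± 119, the cytokinesis motor Kif23 from 669 ± 147 to 309 ± 23.4 and the cyclin Ccnb2 from 848 ± 271 to 347 ± 41.6 (SD, n = 3 each). Top2a, which untangles DNA in dividing cells, had means of 1612 in control and 815 in Klf5 LKO and did not pass (adjusted p = 0.0610), but passed with DESeq2 (adjusted p = 0.000407), at a mean of at least 50 (0.0312) and after thinning (0.0431). Of the 42 genes for S phase and DNA replication, all measured, 41 had lower means (median log2 fold change -0.50). The list was called (adjusted p = 7.29e-17; adjusted p = 0.658 with an estimated correlation). In it 2 genes fell, 0 rose and 40 did not pass, and adjusted over the list alone 17 fell and 0 rose. The 2 were Clspn, an adaptor of the replication checkpoint, from 171 ± 19.0 to 40.3 ± 7.95, and Rrm2, a subunit of ribonucleotide reductase, from 1298 ± 239 to 604 ± 123. The replication clamp Pcna had means of 2817 and 2095 (adjusted p = 0.287), and Ccnd1, a G1 cyclin counted in the Wnt list, 2483 and 2567 (adjusted p = 0.961).

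The calls of these cell cycle genes mostly ended when 1 library was left out. Without control 2 all 6 lost them, with adjusted p = 0.198 for Ccnb1, 0.167 for Mki67, 0.208 for Kif23, 0.254 for Ccnb2, 0.162 for Clspn and 0.162 for Rrm2. All 6 also lost them without Klf5 LKO 2 (adjusted p from 0.0551 to 0.0823), Klf5 LKO 3 (from 0.0704 to 0.151) and control 1 (from 0.0972 to 0.243). Without control 3 this held for Ccnb1 (adjusted p = 0.0522), Kif23 (0.0911) and Clspn (0.0835), and without Klf5 LKO 1 for Ccnb2 (0.0537). The log2 fold changes of all 6 stayed negative whichever library was left out. They ranged from -1.44 to -1.09 for Ccnb1, -1.07 to -0.74 for Mki67 and -1.21 to -0.92 for Kif23. For Ccnb2, Clspn and Rrm2 they ranged from -1.54 to -1.07, -2.22 to -1.96 and -1.26 to -0.95. Both lists remained called without each library in turn, with the preset correlation, and the weakest values were without control 2 (adjusted p = 1.13e-24 for G2/M and 6.45e-10 for S phase). With an estimated correlation neither was called whichever library was left out, and without control 2 they had adjusted p = 0.321 and 0.730. The libraries also differed in leukocyte transcripts: a score over 9 leukocyte genes, the mean of log2 values, was 6.82, 3.88 and 4.55 in Klf5 LKO and 8.36, 7.04 and 4.31 in control. With this score as a term, added after seeing the data, all 6 cell cycle genes fell short of the threshold, with log2 fold changes such as -0.84 (SE 0.19) for Mki67 and -0.99 (SE 0.23) for Ccnb2 against -0.92 (SE 0.17) and -1.24 (SE 0.25) without it. The G2/M and S phase lists stayed past it with the preset correlation (adjusted p = 6.88e-25 and 2.88e-11) and not with an estimated one (adjusted p = 0.425 and 0.508).

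**Figure D3:**
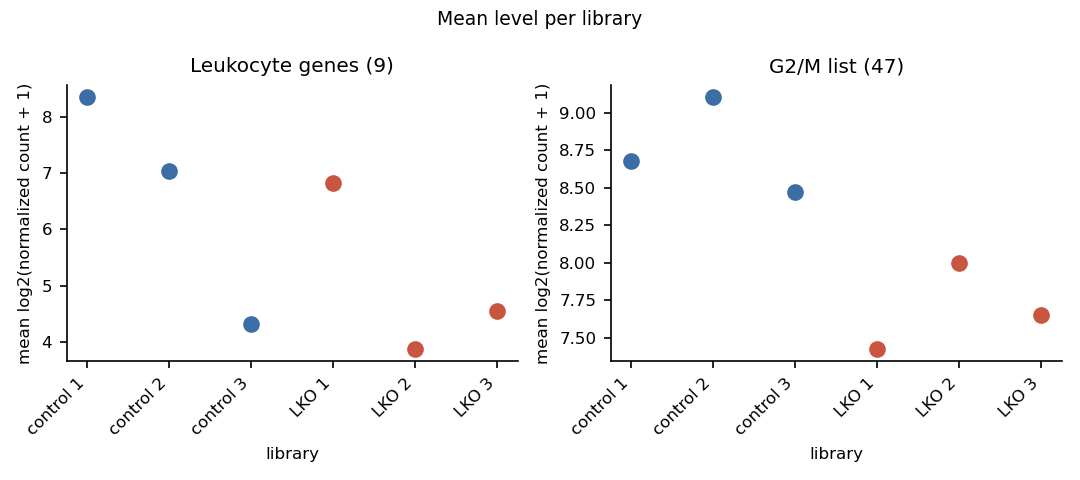
Mean log2(normalised count + 1) over 9 leukocyte genes and over 47 G2/M genes in each of the 6 libraries, with 1 point per library. The G2/M means lay at 7.43 to 7.99 in Klf5 LKO and at 8.47 to 9.10 in control, while the leukocyte means of the 2 groups overlapped.

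Among 27 measured cell cycle inhibitors and p53 targets, 2 rose, 0 fell and 25 did not pass, and adjusted over the list alone 2 rose and 2 fell. The 2 were Gdf15 and Plk2, a stress-induced polo-like kinase, which rose from 3278 ± 462 to 6023 ± 1003. The list was not called (adjusted p = 0.709). Gdf15 was also the only gene to pass among 38 growth factors and receptors, where 1 rose, 0 fell and 37 did not pass, and adjusted over the list alone 2 rose and 0 fell (list adjusted p = 0.477). The call of Plk2 ended without Klf5 LKO 3 (adjusted p = 0.0803), control 1 (0.150) and control 2 (0.107), and that of Gdf15 ended when any library but Klf5 LKO 2 was left out, with adjusted p up to 0.151 without control 1.

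The marker genes of biliary epithelium moved both ways. Of 42 measured biliary markers, 3 rose, 2 fell and 37 did not pass, and adjusted over the list alone 5 rose and 7 fell. Among those that fell, the tetraspanin Tspan8 went from 10414 ± 756 to 6318 ± 808. Sctr, the receptor for secretin, rose from 701 ± 16.5 to 1205 ± 36.6, and the keratin Krt23 from 2309 ± 57.9 to 3523 ± 17.3 (SD, n = 3 each). The other increase was Dcdc2a, chosen after its values were seen, from 5888 to 9023, whose call ended when any library but Klf5 LKO 1 was left out (adjusted p from 0.0997 without Klf5 LKO 2 to 0.228 without control 1). It also ended with no filter (adjusted p = 0.0675), edgeR (0.0550) and the leukocyte term (0.0937), where the log2 fold change was 0.56 (SE 0.13) against 0.61 (SE 0.12). The ductal keratins Krt19 and Krt7 had means of 13695 and 9778 in control and 8345 and 6390 in Klf5 LKO and did not pass (adjusted p = 0.0988 and 0.0720), but passed with DESeq2 (adjusted p = 0.00192 and 0.000905), and Krt7 passed without Klf5 LKO 2 (adjusted p = 0.0295). Epcam had 27512 ± 1936 in control and 25017 ± 1441 in Klf5 LKO (adjusted p = 0.750), and the ductal transcription factor Sox9 8852 ± 2172 and 9586 ± 320 (adjusted p = 0.806). The list was not called (adjusted p = 0.883). Sctr, Krt23 and Tspan8 lost their calls when any library but Klf5 LKO 1 was left out, with adjusted p up to 0.155, 0.162 and 0.162, each without control 2, and down to 0.0754, 0.0728 and 0.0540. Their log2 fold changes moved little when 1 library was left out. They ranged from 0.76 to 0.80 for Sctr, 0.59 to 0.62 for Krt23 and -0.82 to -0.64 for Tspan8.

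In bile duct transport, 28 genes were measured, of which 1 rose, 2 fell and 25 did not pass, and adjusted over the list alone 2 rose and 3 fell. The calcium-activated potassium channel Kcnn4 fell from 5203 ± 437 to 2773 ± 426 and the calcium-activated chloride channel Ano1 from 7557 ± 455 to 4420 ± 612 (SD, n = 3 each), and the gene that rose was Sctr. The list was not called (adjusted p = 0.420). The calls of both channels ended without control 1 (adjusted p = 0.0792 and 0.136) and control 2 (0.0686 and 0.133), that of Ano1 also without Klf5 LKO 3 (0.0704), and that of Sctr without each library but Klf5 LKO 1, with adjusted p up to 0.155 without control 2. None of 38 measured cell junction genes passed, while adjusted over the list alone 1 rose and 3 fell (list adjusted p = 0.211). The tight junction gene Cldn2 had means of 14688 in control and 10348 in Klf5 LKO and the desmosomal Dsg2 27805 and 40253 (adjusted p = 0.113 and 0.129). DESeq2 passed both (adjusted p = 0.00393 and 0.00154), and Cldn2 passed without Klf5 LKO 1 (adjusted p = 0.0323). None of 43 measured primary cilium genes passed, and adjusted over the list alone 0 rose and 0 fell (list adjusted p = 0.432). The members with the smallest p were Pkhd1, with means of 4542 and 5570, and Ift43, with 788 and 1036.

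The Wnt ligands Wnt7b and Wnt7a, secreted signalling proteins, were the 2 of 32 measured Wnt pathway genes that fell, 0 rose and 30 did not pass. Wnt7b fell from 2321 ± 68.0 to 1323 ± 248 and Wnt7a from 552 ± 327 to 118 ± 56.1 (SD, n = 3 each). Adjusted over the list alone 2 rose and 2 fell, and the list was not called (adjusted p = 0.943), with a median of 0.04 although the test pointed down. The calls of both ended without Klf5 LKO 3 (adjusted p = 0.0962 and 0.116), control 1 (0.152 and 0.0834), control 2 (0.155 and 0.0905) and control 3 (0.128 and 0.127), and that of Wnt7a also without Klf5 LKO 2 (0.0856). Both ended with the leukocyte term (adjusted p = 0.0738 and 0.0633), while the log2 fold changes were -0.83 (SE 0.18) and -2.31 (SE 0.46), against -0.83 (SE 0.15) and -2.17 (SE 0.41) without it. That of Wnt7a also ended with no filter (0.0675), edgeR (adjusted p = 0.0501) and voom (0.0809). No gene passed among 26 measured Notch genes, 31 YAP/TAZ and Hippo genes, 16 other KLF and SP family genes or 36 cytokines and chemokines. Adjusted over the list alone, 0, 1, 0 and 5 of them rose and 0 fell in each. The list tests gave adjusted p = 0.663, 0.432, 0.165 and 0.560, and the cytokine median was -0.04 although its test pointed up. The KLF and SP list was called with no filter on low genes (adjusted p = 0.0389; adjusted p = 0.508 with an estimated correlation). Means in control and Klf5 LKO were 241 and 135 for the Notch target Nrarp, 334 and 245 for the ligand Dll1, 17717 and 31126 for the YAP target Cyr61 and 5894 and 8311 for Ankrd1. Among the KLF and SP genes they were 302 and 472 for Sp4, 517 and 814 for Klf9, 152 and 250 for Klf4 and 9562 and 11978 for Klf6. The growth factor Csf1 had means of 1813 and 3228 (adjusted p = 0.0841) and passed without Klf5 LKO 3 (adjusted p = 0.0213), and the chemokine Ccl5 had 107 and 326 (adjusted p = 0.0935). DESeq2 passed Cyr61, Csf1 and Ccl5, with adjusted p = 0.000761, 0.000681 and 0.00477.

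Interferon-induced genes were higher as a list in Klf5 LKO (adjusted p = 0.000183; adjusted p = 0.742 with an estimated correlation), with 27 of 39 means higher. Of the 39 measured members 2 rose, 0 fell and 37 did not pass, and adjusted over the list alone 4 rose and 0 fell. Rsad2 rose from 164 ± 26.0 to 498 ± 88 and Ifit1, which binds viral RNA, from 283 ± 89.5 to 687 ± 146 (SD, n = 3 each). Of 34 immediate early and dissociation response genes, which are induced when tissue is taken apart, 1 rose, 0 fell and 33 did not pass, and adjusted over the list alone 3 rose and 0 fell. That list was called upward (adjusted p = 0.000325; adjusted p = 0.501 with an estimated correlation). Of 31 unfolded protein response genes 1 rose, 0 fell and 30 did not pass, and adjusted over the list alone 2 rose and 0 fell (adjusted p = 0.0307; adjusted p = 0.658 with an estimated correlation). In both the gene that rose was Ppp1r15a, which restores translation after stress, from 1053 ± 79.6 to 2400 ± 747. The interferon list lost its call without control 3 (adjusted p = 0.0731), the immediate early list without Klf5 LKO 3 (0.0720), and the unfolded protein list without Klf5 LKO 1 (0.201) or control 3 (0.101). The call of Rsad2 ended without control 2 (adjusted p = 0.0588) and that of Ifit1 without each of the 6 libraries (from 0.0502 to 0.167). That of Ppp1r15a ended without each library but Klf5 LKO 2, with adjusted p from 0.0544 without Klf5 LKO 1 to 0.152 without control 1. The median log2 fold changes of the 3 lists were small, at 0.23, 0.16 and 0.09. Mean log2 values of the interferon list overlapped between groups, at 8.92, 8.96 and 8.77 in Klf5 LKO and 8.78, 8.76 and 8.24 in control. Among all splits of the 6 libraries into 3 and 3, the largest interferon median, 0.245, set Klf5 LKO 1, Klf5 LKO 2 and control 1 against the rest. The largest immediate early median, 0.199, set Klf5 LKO 1, Klf5 LKO 3 and control 3 against the rest.

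The lists for mitochondrial respiration and glycolysis were called with small downward shifts and no called member. Of 52 measured genes of mitochondrial respiration 0 passed, over all genes or adjusted over the list alone, while 45 of 52 means were lower with a median log2 fold change of -0.07. The list was called (adjusted p = 0.0307; adjusted p = 0.770 with an estimated correlation). Of 24 measured glycolysis genes 0 passed, and adjusted over the list alone 2 fell and 0 rose. That list was called (adjusted p = 0.0475; adjusted p = 0.742 with an estimated correlation), with a median of -0.11. The mitochondrial call ended without Klf5 LKO 1 (adjusted p = 0.432), Klf5 LKO 2 (0.409) or control 1 (0.831), with edgeR (0.0603) and with the leukocyte term (0.349). The glycolysis call ended without Klf5 LKO 1 (0.151), Klf5 LKO 3 (0.186), control 1 (0.0617) or control 2 (0.0941), with a pseudocount of 5 (0.0508), edgeR (0.0598), voom (0.0563) or the leukocyte term (0.0556). Means in control and Klf5 LKO were 3196 and 2183 for the glycolytic enzyme Pkm, 1542 and 827 for the regulator Pfkfb3 and 12863 and 10675 for the ATP synthase subunit Atp5a1. DESeq2 passed Pkm and Pfkfb3 (adjusted p = 0.00526 and 0.00272). None of 36 cholesterol and fatty acid synthesis genes passed, over all genes or adjusted over the list alone (list adjusted p = 0.123), and this list was called downward without control 3 (adjusted p = 0.00134; adjusted p = 0.547 with an estimated correlation). Acss2 had means of 497 and 274 there. Of 36 measured NRF2 and heme stress genes 2 fell, 0 rose and 34 did not pass, and adjusted over the list alone 1 rose and 4 fell (list adjusted p = 0.432). The 2 were the glutathione transferases Gsta4, from 1255 ± 339 to 410 ± 39.4, and Gstm2, from 661 ± 97.1 to 290 ± 64.9. Gsta4 kept its call whichever library was left out, and Gstm2 lost it without each but Klf5 LKO 1, with adjusted p from 0.0565 without Klf5 LKO 2 to 0.146 without control 2.

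**Figure D4:**
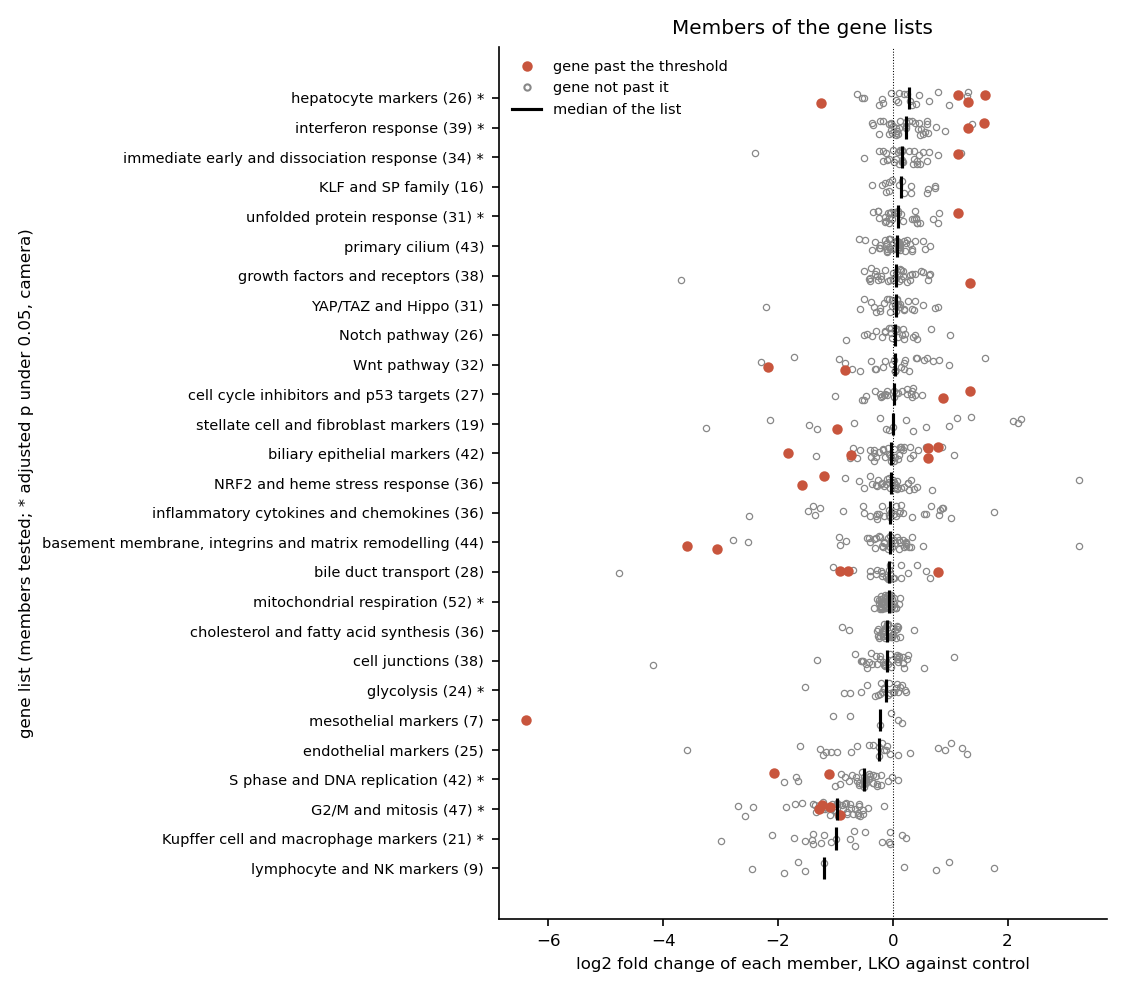
Log2 fold change of Klf5 LKO over control for each measured member of 27 gene lists, with a bar at the list median, called genes in red and a star on each of the 9 lists called with the preset correlation. The G2/M list had the lowest median among the pathway lists, at -0.96, and none of the 9 was called with an estimated correlation.

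Markers of other liver cells were measured to describe what else the preparations held. Whether the biliary cells express some of these genes themselves was not tested, so a marker's level does not measure the content of another cell type. Of 26 measured hepatocyte markers 3 rose, 1 fell and 22 did not pass, and adjusted over the list alone 6 rose and 3 fell. The list was called upward (adjusted p = 0.0126; adjusted p = 0.691 with an estimated correlation). The 3 were Serpina1b, Serpina1c and the plasma protein Ahsg, from 2807 ± 741 to 6192 ± 1621, and the lipoprotein gene Apob fell from 725 ± 83.8 to 314 ± 91.4 (SD, n = 3 each). The most abundant hepatocyte marker was transferrin, Trf, at 38354 ± 8808 in control and 52325 ± 10245 in Klf5 LKO, which did not pass (adjusted p = 0.416). Other hepatocyte transcripts were far lower, with means in control and Klf5 LKO of 8188 and 7240 for Alb and 13.3 and 37.4 for Apoa1. The list call ended without Klf5 LKO 1 (adjusted p = 0.114), Klf5 LKO 3 (0.0720) or control 2 (0.0559). Ahsg and Apob lost theirs without Klf5 LKO 3 (adjusted p = 0.138 and 0.0962), control 2 (0.182 and 0.124) and control 3 (0.129 and 0.136), Ahsg also without Klf5 LKO 1 (0.0736) and Apob without control 1 (0.152), while Serpina1b lost its own without control 2 (0.0588).

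Of 21 measured Kupffer cell and macrophage markers 0 passed, and adjusted over the list alone 1 fell and 0 rose. The means of 19 of the 21 were lower, the median log2 fold change was -0.98, and the list was called (adjusted p = 0.00466; adjusted p = 0.770 with an estimated correlation). The call ended without Klf5 LKO 2 (adjusted p = 0.287) or control 1 (0.244), and with the leukocyte score as a term the direction turned (adjusted p = 0.831). Cd14 had means of 9226 in control and 5847 in Klf5 LKO (adjusted p = 0.0595) and passed without Klf5 LKO 1 (adjusted p = 0.0387), without control 3 (0.0491) and with DESeq2 (0.000218). Fcer1g had 109, 56.9 and 14.2 in control libraries 1 to 3 and 52.6, 4.47 and 3.19 in Klf5 LKO, so that its log2 fold change ranged from -3.26 without Klf5 LKO 1 to -1.43 without Klf5 LKO 3. The most abundant member, Cd74, which chaperones class II antigen molecules, had 14246 ± 9939 in control and 11862 ± 6163 in Klf5 LKO (adjusted p = 0.977), with 18924, 7572 and 9091 in Klf5 LKO libraries 1 to 3 and 24233, 14148 and 4357 in control. The pan-leukocyte gene Ptprc had 97.8, 12.7 and 34.1 in Klf5 LKO and 326, 258 and 16.3 in control, so the libraries differed more within a group than the group means did. The mean leukocyte score was 5.08 in Klf5 LKO and 6.57 in control, a difference of -1.49 (SE 1.49) with an exact two-sided permutation p = 0.4, where 3 against 3 cannot give less than 0.1. On the leading principal component, 33.4% of the variance, Klf5 LKO 1 stood apart at 46.1, with Klf5 LKO 2 and 3 at 2.43 and 10.4 and the controls between -20.6 and -18.6. On component 2, 27.7% of the variance, control 1, control 2 and Klf5 LKO 1 lay at 26.0, 15.6 and 20.5. These are the libraries with the highest leukocyte scores. Control 3 lay at -8.90 and Klf5 LKO 2 and 3 at -27.0 and -26.2.

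No gene passed among 9 measured lymphocyte and NK markers (adjusted over the list alone 1 rose and 0 fell; list adjusted p = 0.943, pointing up while the median was -1.20) or 25 endothelial markers (0 adjusted over the list alone; list adjusted p = 0.420). The endothelial list was called downward without control 1 (adjusted p = 0.0298) and with the leukocyte term (adjusted p = 0.00201). With an estimated correlation it was called in neither (adjusted p = 0.769 and 0.425). Of 19 measured stellate cell and fibroblast markers 1 fell, 0 rose and 18 did not pass, and adjusted over the list alone 1 rose and 2 fell (list adjusted p = 0.943). That gene was the matrix protein Fbln2, from 10176 ± 1690 to 5188 ± 840 (SD, n = 3 each), whose call ended without Klf5 LKO 3 (adjusted p = 0.0659), control 2 (0.0905) or control 3 (0.0611). Of 7 measured mesothelial markers, Msln fell, 0 rose and 6 did not pass, and adjusted over the list alone 2 fell and 0 rose (list adjusted p = 0.182). The call of Msln ended without Klf5 LKO 3, control 1, control 2 or control 3, with adjusted p = 0.0687, 0.150, 0.155 and 0.127. Neutrophil markers and erythrocyte and platelet markers had 4 and 3 measured members, too few for the list test, and none of them passed over all genes or adjusted over the list alone. Low values varied widely between libraries of a group. The neutrophil gene Il1r2 had 152, 55.3 and 16.3 in control libraries 1 to 3 and 38.6, 0 and 16.0 in Klf5 LKO, and Mmp9 had 42.3, 17.4 and 9.14 in control and 0, 42.5 and 0 in Klf5 LKO. The lymphocyte gene Ebf1 had 122, 49.0 and 44.7 in control and 173, 132 and 93.7 in Klf5 LKO. The endothelial gene Stab1 had 55.2, 47.4 and 143 in control and 243, 133 and 149 in Klf5 LKO. Pecam1, also endothelial, had 37.7, 19.0 and 34.5 in control and 0, 6.71 and 1.06 in Klf5 LKO. Its groups did not overlap, though at these low counts it did not pass (adjusted p = 0.231). The most abundant endothelial and stellate list members were Podxl, with means of 1708 in control and 1346 in Klf5 LKO, and Gas6, at 19509 and 18606, and the platelet gene Pf4 had 170 and 117 and Bpgm 475 and 506.

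The authors' deposited table of the same comparison gave adjusted p-values for 13184 genes, of which 119 were higher and 199 lower in Klf5 LKO at 0.05, 318 in all. The authors' deposited table also called 87 of the 88 genes, all but Msln. Over 13490 genes compared, 96.3% had the same sign in the authors' deposited table as in the limma fit. Its fold changes were smaller, with a median ratio of 0.807 over the 88 genes, and for Klf5 the authors' deposited table gave a log2 fold change of -0.83.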

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

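The leukocyte term, the thinning of reads and the estimated correlation within each other setting were chosen only after the values were seen, and the other settings were planned. All 88 called genes kept their direction in every setting. Of the 40 named called genes besides Klf5, the number that stayed called was 40 with TMM factors, 39 with upper-quartile scaling, 24 with no filter, 40 at a mean of at least 50, 37 and 40 with pseudocounts of 0.5 and 5, 39 with DESeq2, 36 with edgeR, 29 with voom, 38 after thinning and 23 with the leukocyte term. The calls that ended were those of Ifit1 with upper-quartile scaling, of Msln, Ifit1 and Ccnb2 with a pseudocount of 0.5, of Msln with DESeq2, of Samd5, Ifit1, Wnt7a and Ahsg with edgeR, and of Samd5 and Ccnb2 after thinning. With voom they were those of Mgat3, Samd5, Cdsn, Gdf15, Ifit1, Gpc3, Ppp1r15a, Kif23, Ccnb2, Wnt7a and Ahsg (adjusted p from 0.0551 to 0.0847). With no filter they were those of Msln, Samd5, Cdsn, Gdf15, Ifit1, Gpc3, Ppp1r15a, Clspn, Ccnb1, Mki67, Kif23, Ccnb2, Wnt7a, Gstm2, Apob and Ahsg (from 0.0522 to 0.0866). With the leukocyte term they were those of Cdsn, Gdf15, Gpc3, Clspn, Rrm2, Ccnb1, Mki67, Kif23, Ccnb2, Plk2, Tspan8, Sctr, Krt23, Wnt7b, Wnt7a, Ano1 and Gstm2 (from 0.0633 to 0.102). Over the 88 genes this term ended 42 calls, while the log2 fold change was larger in size in 40 (median ratio 0.994) and its SE was larger in 76. The number that stayed called was 34, 25 and 15 without Klf5 LKO 1, 2 and 3, and 14, 7 and 20 without control 1, 2 and 3. Of the 40 named genes that were not called, DESeq2 called 11, a mean of at least 50 called 4 (Csf1, Cd14, Krt7 and Top2a), thinning 3 (Ccl5, Cd14 and Top2a) and the leukocyte term 2 (Ccl5 and Pfkfb3). Both other scalings left all 27 lists in their direction and on their side of the threshold, and moved the median log2 fold change of all genes from -0.01 to at most -0.02.

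Genes called numbered 335 with DESeq2 (119 higher, 216 lower) and 182 at a threshold of 0.1, and with no filter 13 were higher. Leaving out 1 library gave 14 to 105 genes, 1 to 22 higher and 13 to 83 lower, and 5 to 8 lists. With an estimated correlation, over all libraries or in any other setting but DESeq2, where none was estimated, 0 lists were called, and 0 with fry. Klf5 ranged from -0.98 to -0.84 without 1 library. Leaving out a library leaves fewer samples, and a threshold of 0.1 is looser by construction. For the others the cause was not tested.

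The replicate number as a term (the replicate block) gave 110 genes (27 higher, 83 lower), 79 of them among the 88, and 9 lists. Of the 40 named called genes 36 stayed called, and Krt23 (adjusted p = 0.0515), Gpc3 (0.0520), Gstm2 (0.0502) and Ifit1 (0.0654) did not, while Top2a (0.0297) and Cyr61 (0.0177) passed. Deviations of same-numbered libraries correlated at 0.187, -0.012 and 0.125. Klf5 LKO 1 correlated at 0.049 and -0.204 with controls 2 and 3, and Klf5 LKO 3 at -0.097 and -0.050 with controls 1 and 2. Klf5 LKO 2 correlated best with control 3 (0.127), so whether the numbers pair the samples stayed open. Under the block the estimated correlation was 0.044 for the S phase list and 0.054 for G2/M, against 0.456 and 0.317 without it. Neither list was called with that correlation (adjusted p = 0.287 each). Under the replicate block the Wnt and lymphocyte lists turned direction without a call (adjusted p = 0.988 and 0.702).

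Other reversals were of results that were not called in that setting. With the leukocyte term the log2 fold change was 0.76 for Cd74 and -0.01 for Sox9, and the lists for growth factors, YAP/TAZ and stellate cells (adjusted p = 0.996 each) and macrophages (0.831) turned. The macrophage list shares 6 genes with the leukocyte score, so its turn was built into the term. Thinning turned Bpgm to -0.029 and the Wnt list (0.928). No filter turned the Wnt (0.914), stellate (0.914) and lymphocyte (0.446) lists, voom the Wnt list (0.984), a mean of at least 50 the endothelial list (0.964), DESeq2 and edgeR the stellate list (0.946 and 0.904), and fry the biliary, stellate (0.983 each) and lymphocyte (0.947) lists. Without 1 library the log2 fold changes ranged from -0.76 to 0.48 for Cd74, -0.15 to 0.0038 for Gas6, -0.19 to 0.25 for Bpgm and -0.11 to 0.20 for Ccnd1. Adjusted p ranged from 0.364 to 0.928 for the inhibitor and p53 list, 0.509 to 0.975 for biliary, 0.581 to 0.904 for Wnt, 0.155 to 0.904 for NRF2, 0.00134 to 0.861 for cholesterol, 0.107 to 0.904 for lymphocyte, 0.0298 to 0.904 for endothelial and 0.509 to 0.970 for stellate lists. The cause was not tested. Depth limits low genes most: at 11726934 reads, control 2 was the shallowest library.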

Other observations

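The gene groups in this and the following paragraph, the tests of the Serpina1 genes, of the leukocyte score and of the G2/M median without each library, the leukocyte term and the thinning were chosen only after the values were seen. Outside the fixed lists, the potassium channel gene Kcnq1 fell from 1717 ± 119 to 481 ± 59.4 normalised counts (SD, n = 3 each; adjusted p = 0.000203), Gabrp, a subunit of a chloride-conducting receptor, from 1830 ± 707 to 335 ± 180 (adjusted p = 0.00939), and the sodium pump regulator Fxyd3 from 1337 ± 318 to 583 ± 109 (adjusted p = 0.0229). Like Kcnn4, Ano1 and Fxyd6, these are genes of ion channels or pump regulators, a group that was not tested for enrichment. Kcnq1 kept its call whichever library was left out. That of Gabrp ended without control 1 (adjusted p = 0.0623) or control 2 (0.0681), and that of Fxyd3 without Klf5 LKO 2 (0.0579), control 1 (0.136) or control 2 (0.114) and with the leukocyte term (0.0633), where its log2 fold change was -1.09 (SE 0.22) against -1.19 (SE 0.20). Beside the laminin chains Lamb3 and Lama3, the integrin genes Itgb4 and Itga6, which code for a laminin receptor, had means of 2852 and 2821 and of 2718 and 2427 in control and Klf5 LKO, and neither passed.

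Other called genes included the cathepsin Ctse, which fell from 2014 ± 562 to 489 ± 166, the metalloprotease Adam8, which fell from 1096 ± 212 to 255 ± 95, and the apoptosis inhibitor Birc2 and the cyclin Ccnd2, which rose from 3685 ± 482 to 6573 ± 1000 and from 1498 ± 345 to 2889 ± 327. Adam8 kept its call whichever library was left out. That of Ctse ended without control 2 (adjusted p = 0.0588), that of Birc2 without control 1 (0.150), control 2 (0.0629) or control 3 (0.0907), and that of Ccnd2 without Klf5 LKO 2 (0.0610), control 1 (0.137) or control 2 (0.136) and with the leukocyte term (0.0718), where its log2 fold change was 0.90 (SE 0.19) against 0.97 (SE 0.17). Among 389 families of genes with a shared symbol stem, camera placed Serpina higher (6 of 6 members, median log2 fold change 1.30, adjusted p = 1.32e-05), and the gap junction genes Gjb (5 of 5, median -1.01, adjusted p = 0.000349), ribosomal protein genes Rpl (43 of 46, median -0.22, adjusted p = 0.000871), Mcm (9 of 10, median -0.50, adjusted p = 0.00591) and Serpinb (6 of 7, median -0.48, adjusted p = 0.0309) lower. All 5 had adjusted p = 0.989 with an estimated correlation.

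The lower G2/M genes, with a median log2 fold change of -0.96, could reflect fewer dividing leukocytes, more reads in the Klf5 LKO libraries or 1 unusual library. With the leukocyte score as a term the median was -0.99, and between -1.38 and -0.74 with each library left out, which argues against leukocytes as the whole cause. After thinning to equal total reads it was -0.97 (SD 0.0131 over 20 thinnings). Thinning leaves the expected ratio of normalised counts nearly unchanged, so it cannot decide whether depth is the cause. The weakest value without a library was -0.79, without control 2, which argues against 1 library alone as the cause. Klf5 LKO 3 had 17161087 total reads, fewer than control 1 (20066745) and control 3 (17665210). Its mean over the G2/M genes was 7.65 on the log2 scale, against 8.67 and 8.47. The deepest library, Klf5 LKO 2 (24784167 reads), had the highest G2/M mean of its group, 7.99. These values argue against total reads alone as the cause. An effect of Cre, other cell types, and a difference in distinct molecules, which thinning of reads does not equalise, remain open. So does the hypothesis of fewer dividing biliary cells in the absence of Klf5, which was not tested. Among the other splits of the 6 libraries, the median went as far as -0.64. Each of those splits mixes the groups unevenly, so it keeps part of the real difference and does not measure chance alone.

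The higher Serpina1 genes could come from hepatocyte RNA or from reads moved between the near-identical copies. Summed over 5 copies, the Serpina1 genes rose from 1820 ± 113 to 4648 ± 236 normalised counts (SD, n = 3 each), a log2 ratio of 1.35 (SE 0.0664), and a shift of reads between copies would leave the sum unchanged. The hepatocyte marker list was called upward (adjusted p = 0.0126; adjusted p = 0.691 with an estimated correlation). It contains Serpina1a, Serpina1b and Serpina1c, so its call is not separate evidence. Among its other members, Ahsg rose from 2807 to 6192, Apob fell from 725 to 314, and Trf had 38354 and 52325 without a call. Hepatocyte RNA would bring all abundant transcripts. Apoa1, Apoa2, Apoc3, Cyp2e1 and Cps1 together held only 87.2 ± 62.6 in Klf5 LKO and 52.9 ± 11.5 in control (SD, n = 3 each). With Alb, which made up most of the sum at 7240 ± 1711 and 8188 ± 1336, the change of these 6 was -914 (SE 1282), against 2828 for Serpina1, so these values argue against hepatocyte RNA as the whole source. A change of Serpina1 expression in the biliary cells themselves is a hypothesis that remains open, as is an effect of Cre.

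Leukocyte transcripts differed widely between libraries, and might follow the genotype or the cell isolation. The score of 9 leukocyte genes gave an exact permutation p = 0.4 between the groups, where the smallest possible is 0.1, with a difference of -1.49 (SE 1.49), so a genotype difference in leukocyte share cannot be told apart from uneven carry-over with 3 libraries each.

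There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split called 88 genes and the highest other 10, and 1 of the 10 splits gave as many. For lists the real split called 9 and the highest other 13, and 3 of the 10 splits gave as many. The split that called 10 genes set Klf5 LKO 1, control 1 and control 2 against the other libraries, and its median log2 fold change over the 9 leukocyte genes was 3.33. Called genes within 1 Mb of each other and of the same direction made 6 pairs, against a mean of 4.19 and a 95th percentile of 8 in 1000 random sets matched on expression (permutation p = 0.233).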
